A study of Bos taurus with 8 samples.

How the data were processed

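Rumen tissue came from 4 newborn male calves and 4 adult steers, all angus crosses, with 1 library per animal. Per the labels' protocols, total RNA was isolated with TRIzol and a Direct-zol column kit, fragmented and copied with random hexamers. The second strand was made with dUTP, which marks strand, and libraries were amplified in 10 PCR cycles and sequenced from both ends on an Illumina instrument. The submitters' processing notes name Trimmomatic 0.39 (read trimming), STAR 2.7.11a (alignment), featureCounts 2.0.2 (counting) and DESeq2 1.42.0. The genome build and annotation release are not given in the sources used here, so start and end positions are the file's own, 1-based, with no build named.

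The deposited file holds whole-number counts per gene name, not normalised. Per the file headers, the authors counted with featureCounts 2.0.2 over whole transcript spans joined by gene name, so reads in introns count too. No strand option was set, so reads from a gene and its antisense neighbour cannot be told apart. Paired mode was set without counting of read pairs, so both mates of a pair add to a count, and 86.9% to 89% of the counts from 1 to 10 in each library were even. Reads that lie in more than 1 gene were dropped. All 4523 genes whose span lies wholly inside other spans (13.7% of the 33132 genes) therefore had no count, against 4.76% of 6926 genes with a partly shared span and 28.7% of 21683 genes with an unshared span. Of the 1664 genes of the fixed lists, 34 were wholly shared and could not be measured. Near-identical relatives, such as the KRT6 genes, ACTA2 and ACTG2, the globins, ribosomal proteins, metallothioneins and beta-defensins, can share or lose reads, and their values are uncertain. A reference table of the ARS-UCD2.0 assembly was used for names, gene types and chromosome numbers only, and 27621 symbols (83.4%) matched it. The chromosome number of each sequence in the count file is that of most of its matched symbols.

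Library totals were 42322022 to 54449684 counts. CPM was computed from the deposited counts with TMM-scaled library sizes. The smallest chi-square per degree of freedom between libraries of a group was 113, so no library was a repeat of another. Group values are means ± SD over 4 animals. For a gene at 0 in all libraries of a group, the fold is a bound from a floor of 3 counts in each library, and for 1 to 3 counts a ratio with an exact 95% interval is given, over counts halved and rounded up in each library, as pairs. Intervals and floors cover counting error only. The floor is in single counts, so with 3 pairs per library as the floor the bounds would be 2-fold smaller.

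Steers were compared with calves in edgeR 4.0.16 (R 4.3.3): filterByExpr by group, TMM, quasi-likelihood fit with robust dispersion, F test, Benjamini-Hochberg adjusted p under 0.05, and log2 fold change as steer minus calf. SE is the log2 change divided by the square root of F. The filter left 16326 genes, and 11084 genes had no count in any library. The common biological coefficient of variation was 41.8%. Gene lists (44) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry beside it, and calls were also counted with p adjusted over the list alone. Adjusted p-values printed for genes are from edgeR and those for lists are from camera unless another tool is named. Mean log2 CPM of each list was compared with a two-sided exact permutation test over the 8 libraries.

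The gene lists, the transcription factor list, the tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 highest and 10 lowest log2 changes among called genes with a symbol, non-overlapping groups and a mean of at least 10 CPM in the higher group. It added the 5 most abundant called genes in each direction changed at least 2-fold, up to 3 called members per list and direction, the 6 highest and 6 lowest called transcription factors with at least 1 CPM, 16 genes whatever their result, and the most abundant member of a list with no call. Of 193 such genes 180 were called. Some of them are not reported here.

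The procedure was tested on simulated counts for this comparison over 16059 genes, with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 10% of the 2-fold and 67% of the 4-fold genes, and 3 unchanged genes (3.75% of calls) were called. With nothing changed, 0 genes and 0 lists were called. Genes were drawn independently of each other, so the 0 lists say nothing on list calls where members move together. Most 2-fold changes went undetected with 4 animals per group in this simulation. Only 200 genes were changed in it, which makes the adjusted cutoff stricter than with the many calls in the real data. Its recovery therefore does not carry over directly. Alternatives were 3 other scalings, 2 filters, no robust dispersion, a replicate block, the 50 most abundant genes left out, each library left out, an adjusted p under 0.01, glmTreat against a 2-fold change, DESeq2 1.42.0 and limma-voom. Halved counts, the smooth muscle mean or the slope of log2 CPM on gene span as a covariate, calf 2 and steer 4 left out together, and unshared spans only were added after the data were seen. A planned search for promoter motifs needs a genome sequence and was not run.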

Results

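RNA was sequenced from rumen tissue, the large fermentation chamber of the ruminant stomach, of 4 newborn male calves and 4 adult steers (castrated males), all angus crosses. The series asks which genes, signalling pathways and transcription factors accompany the growth of the rumen after birth, and the design gives 1 comparison, adult steer against newborn calf. Calves differ from steers in age and castration together, and no label gives diet or batch. Over 33132 genes, calves 1 to 4 had 46586195, 47200576, 45779990 and 49628428 counts. Steers 1 to 4 had 47104700, 42322022, 47465916 and 54449684 counts. Log2 CPM, the log of counts scaled by library size, correlated across genes at 0.941 to 0.966 between calves, 0.907 to 0.962 between steers and 0.846 to 0.891 between the groups. The first principal component held 54.4% of the variance and separated all 4 calves from all 4 steers.

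Of 16326 genes tested with edgeR's quasi-likelihood test, 2752 differed between the groups at a Benjamini-Hochberg adjusted p under 0.05. Of these, 1257 were higher and 1495 lower in steers, and 2292 changed at least 2-fold (997 higher, 1295 lower). The CPM of the 2 groups did not overlap for 2549 of the called genes (92.6%) and for 23.3% of all tested genes, where chance gives 2.86%. Scaling by library size alone gave 835 higher and 1555 lower genes, so that 34.9% of calls were higher instead of 45.7%, and it shifted the median log2 fold change of all genes by -0.11. The test was run on 4 animals per group, so its p-values measure the spread between animals, and the count of called genes fell to 1734 without calf 1.

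Among called genes with at least 10 CPM in calves and groups that did not overlap, the steepest losses in steers were mostly in squamous epithelial genes. KRT4, a keratin of the upper layers of moist squamous epithelia, lies on chromosome 5 from 27117923 to 27124834 in the coordinates of the count table, whose genome build is not given in the sources used here. It took 2.59% to 4.52% of all counts in calves and at most 0.000288% in steers. Its level fell from 37740 ± 12350 to 1.374 ± 1.673 CPM (SD, n = 4 per group). Its partner keratin KRT13 (chromosome 19, 41708628 to 41713169) fell from 29700 ± 10120 to 522 ± 324 CPM, a log2 change of -5.83 ± 0.63 (SE, adjusted p = 0.000449). MUC21, a cell-surface mucin (chromosome 23, 28105124 to 28109719), had 332 ± 202 CPM in calves and no count in any steer, at least 4966-fold lower when each steer library is given a floor of 3 counts. KRTDAP, a keratinocyte differentiation protein, fell by 13.17 ± 0.68 on the log2 scale. CRNN, a protein of differentiated squamous cells, had 14706 counts in calves against 2 in steers. Both mates of a read pair were counted, so the ratio was taken over pairs, 7354 against 1, which gives 6931 with a 95% counting interval of 1244 to 273800. The flavin monooxygenase FMO2 had 2083 pairs in calves and 2 in steers, a ratio of 981.6 (271.4 to 8111). The cornified envelope gene RPTN and the mucosal scavenger receptor DMBT1 had log2 changes of -9.87 and -10.65. ASPRV1 and LOR, both of the cornified layer, also had no count in steers (at least 160.2-fold and 634.3-fold lower), but calf 2 held most of their counts, with 160 CPM of LOR against 0.418 to 7.83 in the other calves. The LOR call ended without calf 1, steer 1, steer 2 or steer 3, with DESeq2 or limma-voom and with no filter. Without calf 2 the fitted changes were -10.18 for LOR and -10.01 for ASPRV1, but with no count in steers these sizes are not measured. The bounds would be much smaller without calf 2, as the other calves had only 1.46 to 4.75 CPM of ASPRV1. Leaving out 1 library also moved the fitted log2 change to -15.74 for KRT4 (without steer 2). CRNN without steer 4 (-14.72) and FMO2 without steer 3 (-12.98) had no steer count left, so these fitted sizes are not measured. The fitted change moved to -11.68 for DMBT1 (without steer 2) and -11.37 for RPTN (without steer 4), further from 0 as for KRT4. For DMBT1 it was -9.98 without calf 3, nearer to 0.

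With the same limits, and at least 10 CPM in steers, the largest gains were mostly of other kinds. The beta-defensin DEFB7, below that level, rose by 7.92 on the log2 scale. ADH6, an alcohol dehydrogenase, was at 0.0587 ± 0.0748 CPM in calves and 51.6 ± 77.7 in steers. Steer 1 alone had 165.7 CPM, and ADH6 lost its call with limma-voom. The calf means of DEFB7 and ADH6 lay below the floor of 3 counts per library (0.0615 CPM), so the sizes of their changes are uncertain. The aryl hydrocarbon receptor target CYP1A1 rose by 7.56 ± 0.80, the muscle genes HAND1 and SMYD1 by 7.37 ± 1.15 and 6.83 ± 1.00. The urate pathway enzyme URAD rose by 6.67 ± 0.62, and NYAP2 and CDHR4 by 6.22 ± 0.68 and 6.20 ± 0.53 on the log2 scale. Metallothionein MT1E rose by 6.13 ± 0.63, and the stress keratins KRT6C and KRT6B by 6.01 ± 0.84 and 5.61 ± 0.61. The KRT6 genes and the metallothioneins are near-identical families between which reads can be split, so the share of each member is uncertain. The change of ADH6 was 7.86 without steer 1 and 11.16 without calf 4, that of HAND1 8.51 without calf 2 and 6.75 without steer 3. Without steer 4 the changes were 6.84 for CYP1A1, 5.27 for KRT6C and 4.79 for KRT6B.

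**Figure D1:**
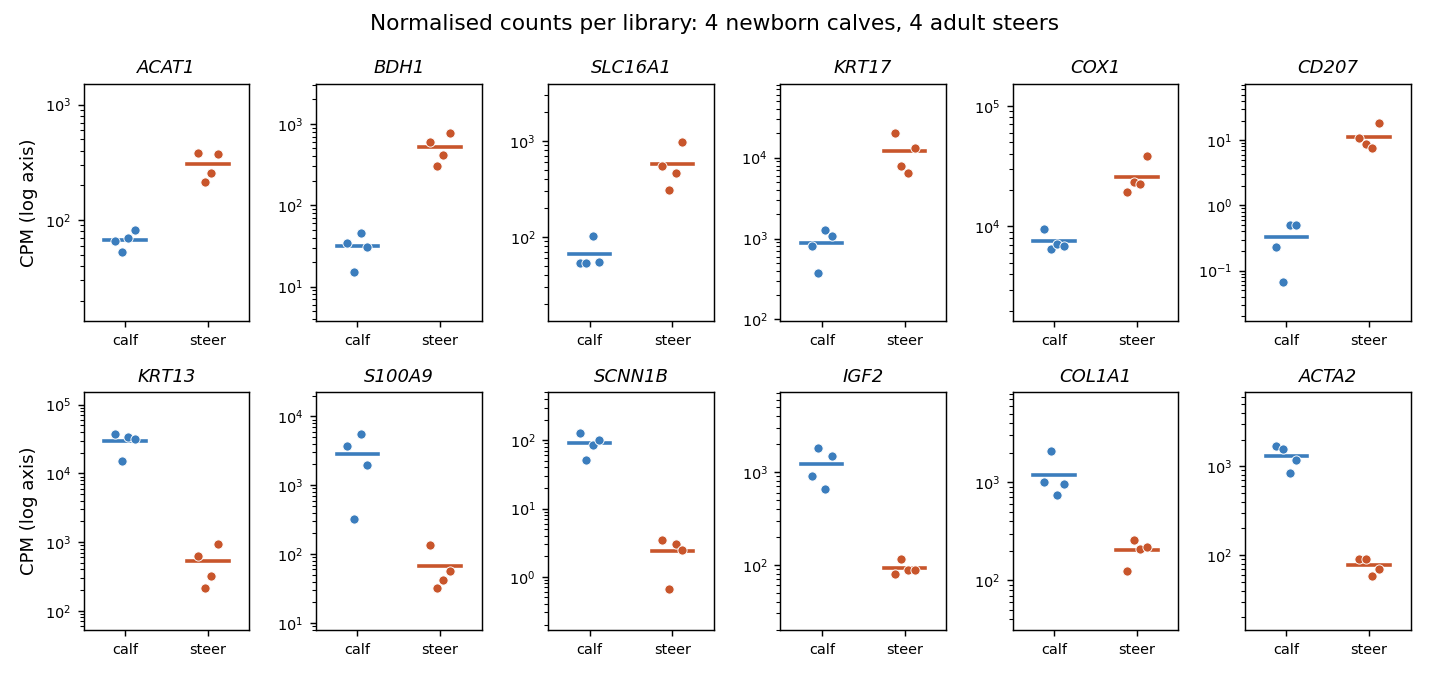
CPM on a log axis for 12 named genes in each of the 8 libraries (points), with the group mean as a line. ACAT1, BDH1, SLC16A1, KRT17, COX1 and CD207 were higher in all 4 steers than in any calf, and KRT13, S100A9, SCNN1B, IGF2, COL1A1 and ACTA2 were lower in all 4 steers.

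Genes that turn short-chain fatty acids, the products of rumen fermentation, into ketone bodies and acetyl-CoA were mostly higher in steers. Of 27 tested members of the list for ketogenesis and short-chain fatty acid oxidation, 17 rose and 3 fell (17 and 4 adjusted over the list alone). The list was higher with camera (adjusted p = 7.78e-07; adjusted p = 0.461 with an estimated correlation). BDH1, which interconverts acetoacetate and 3-hydroxybutyrate (chromosome 1, 71964466 to 72000614), rose from 31.4 ± 12.7 to 525 ± 210 CPM (log2 change 4.07 ± 0.43, adjusted p = 0.000438). ACAT1, a ketone-body thiolase, rose from 67.5 ± 11.9 to 306 ± 82 CPM (2.18 ± 0.26, adjusted p = 0.000717), and PCCA, a subunit of propionyl-CoA carboxylase, rose by 2.27 ± 0.27. AACS, which spends acetoacetate on lipid synthesis, fell by 1.87 ± 0.22, and the propionyl-CoA synthetase ACSS3 changed by -2.99 ± 0.63.

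Transporters moved in both directions. In the list for short-chain fatty acid, bicarbonate and proton transport, 7 of 28 members rose and 6 fell (8 and 9 adjusted over the list alone), and camera called no direction (adjusted p = 0.818). The monocarboxylate transporter SLC16A1 (chromosome 3, 30380729 to 30411748) rose from 66.2 ± 24.5 to 574 ± 288 CPM (3.12 ± 0.41, adjusted p = 0.00123), and its chaperone BSG rose by 1.73 ± 0.35. CA13 and CA8, of the carbonic anhydrase family, fell by 1.97 ± 0.25 and 3.12 ± 0.48. CA12 of that family rose from 0.305 ± 0.150 to 3.35 ± 2.97 CPM (3.45 ± 0.66, and 2.62 without steer 4), with 90.9% of its counted span shared with another gene, APH1B. SLC16A3 stayed at 1.23 ± 0.67 and 1.26 ± 0.20 CPM (adjusted p = 0.966). The sodium-proton exchanger SLC9A3 was at 176 ± 124 CPM in calves and 32.1 ± 47.4 in steers (adjusted p = 0.0989), with 32.7% of its counted span shared with another gene. The urea transporter SLC14A1 was at 47.9 ± 48.0 and 199 ± 123 (adjusted p = 0.122), and the carbonic anhydrase CA1 at 3.50 ± 3.78 and 16.9 ± 12.3 (adjusted p = 0.0643). Without calf 3 the log2 changes of SLC9A3, SLC14A1 and CA1 went from -2.45, 2.06 and 2.27 to -1.83, 2.94 and 3.38, and without steer 4 those of SLC9A3 and CA1 were -4.37 and 1.68. The 3 genes passed with the smooth muscle covariate, SLC9A3 also without steer 4 (with or without calf 2) and with limma-voom, SLC14A1 with DESeq2, and CA1 without calf 3, without steer 2 and with either tool. In the list for urea, water and cation transport, 1 of 27 members rose and 7 fell (1 and 10 adjusted over the list alone; camera adjusted p = 0.0042, lower; adjusted p = 0.461 with an estimated correlation). With the smooth muscle mean as a covariate the list did not pass (0.185). The potassium-chloride cotransporter SLC12A7 rose from 47.4 ± 4.4 to 331 ± 78 CPM, whereas the epithelial sodium channel subunits SCNN1G and SCNN1B fell from 30.6 ± 11.6 to 0.0433 ± 0.0444 and from 90.8 ± 31.3 to 2.41 ± 1.23 CPM. The fitted change of SCNN1G was -9.53 ± 0.68, and -10.34 without steer 1. Its steer mean lay below the floor of 3 counts per library (0.0667 CPM), so the size is uncertain. The sodium pump subunit ATP1B1 fell by 2.52 ± 0.35.

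The 13 mitochondrially encoded genes took 1.81% to 2.56% of counts in calves and 3.92% to 7.69% in steers. Of the 13, 8 rose and none fell (9 and 0 adjusted over the list alone; camera adjusted p = 5.09e-05; adjusted p = 0.461 with an estimated correlation). COX1, a subunit of cytochrome oxidase, rose from 7543 ± 1341 to 25760 ± 8333 CPM and COX3 from 3341 ± 834 to 8395 ± 1688. The call of COX3 was lost without calf 3 and without calf 2 and steer 4 (log2 changes with 1 library left out 1.18 to 1.45). Among nuclear genes of the respiratory chain, 13 of 71 rose and none fell (16 and 0 adjusted over the list alone; camera adjusted p = 1.55e-07; adjusted p = 0.693 with an estimated correlation and 0.091 with fry). They included SDHD (1.55 ± 0.17), UQCRB (1.02 ± 0.22) and SDHC (1.05 ± 0.23). In the list for the tricarboxylic acid cycle, 5 of 18 rose and none fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.00406; adjusted p = 0.461 with an estimated correlation). SUCLG2 (1.82 ± 0.20) and DLD (1.46 ± 0.21) were among those higher. Of the PPAR target and fatty acid oxidation list, 5 of 28 rose and 2 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.195; adjusted p = 0.0298, higher, with fry). The acyl-CoA thioesterase ACOT2 and the lipid droplet protein PLIN2 rose by 2.59 ± 0.31 and 2.31 ± 0.42, and the peroxisomal enzyme EHHADH fell by 2.36 ± 0.22.

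Enzymes that process foreign compounds changed as well. In the xenobiotic and glutathione list 12 of 30 members rose and 3 fell (14 and 5 adjusted over the list alone; camera adjusted p = 0.0102, higher; adjusted p = 0.589 with an estimated correlation and 0.112 with fry). With camera at the preset correlation it was 0.0772 when calf 2 and steer 4 were left out. Besides CYP1A1, the quinone reductase NQO1 and the glucuronosyltransferase UGT1A6 rose by 3.87 ± 0.55 and 3.64 ± 0.60, or by 3.27 and 2.86 without steer 4. ALDH3A1 and CYP2C87 fell by 2.94 ± 0.45 and 2.27 ± 0.35. Of the cholesterol synthesis list none of 23 rose and 3 fell (0 and 3 adjusted over the list alone; camera adjusted p = 0.195, lower at 0.00354 without calf 2, at 0.000176 without calf 2 and steer 4, and at 0.0419 with the gene span slope as a covariate). The genes that fell included CYP51A1 (-2.01 ± 0.58) and DHCR7 (-1.24 ± 0.36), which both lost their calls without calf 1, calf 3, calf 4, steer 1, steer 2 or steer 3. In those fits the log2 changes were -1.99 to -1.71 for CYP51A1 and -1.33 to -1.01 for DHCR7. Without steer 4, CYP51A1 kept its call at -2.89. The call of CYP51A1 also ended with the gene span slope as a covariate, and that of DHCR7 with limma-voom and with the smooth muscle covariate.

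Keratins changed in both directions, and basal keratinocyte markers had no common direction. KRT5, the keratin of basal cells, was at 3161 ± 213 CPM in calves and 3491 ± 604 in steers (adjusted p = 0.755). Of 20 basal keratinocyte markers 3 rose and 4 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.873). KRT17 (chromosome 19, 41834618 to 41846161) rose from 887 ± 394 to 12010 ± 6307 CPM (3.76 ± 0.54, adjusted p = 0.00188), although 36.4% of its counted span lies in another keratin gene, KRT42. The collagens of the basal attachment complex COL17A1 and COL7A1 fell by 1.79 ± 0.27 and 1.23 ± 0.25. Of the cornified layer and barrier list 3 of 37 members rose and 17 fell (4 and 18 adjusted over the list alone; camera adjusted p = 9.22e-10; adjusted p = 0.461 with an estimated correlation). The ceramide synthase CERS3 and SBSN, a protein of differentiated keratinocytes, fell by 5.13 ± 0.36 and 5.42 ± 0.42, while the transglutaminase TGM5 and KRT6A rose by 4.98 ± 0.52 and 3.46 ± 0.57. KRT10, a keratin of dry epidermis, was near 4 CPM in both groups (4.64 ± 1.09 and 4.00 ± 0.51). EVPL, an abundant envelope protein, fell from 1346 ± 275 to 580 ± 259 CPM, a call that ended without calf 1, calf 3, calf 4, steer 2 or steer 3 (-1.02 at the smallest change with 1 library left out), without calf 2 and steer 4 together and with the smooth muscle mean as a covariate. Of the tight and gap junction list none of 23 rose and 7 fell (1 and 11 adjusted over the list alone; camera adjusted p = 0.00117; adjusted p = 0.589 with an estimated correlation and 0.0531 with fry). With the mean of the smooth muscle markers as a covariate the list did not pass (0.372). The connexins GJB5 and GJB6 had changes of -2.82 ± 0.39 and -6.35 ± 1.13, and that of GJB6 was -8.37 without steer 4 and -5.76 without calf 3.

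**Figure D2:**
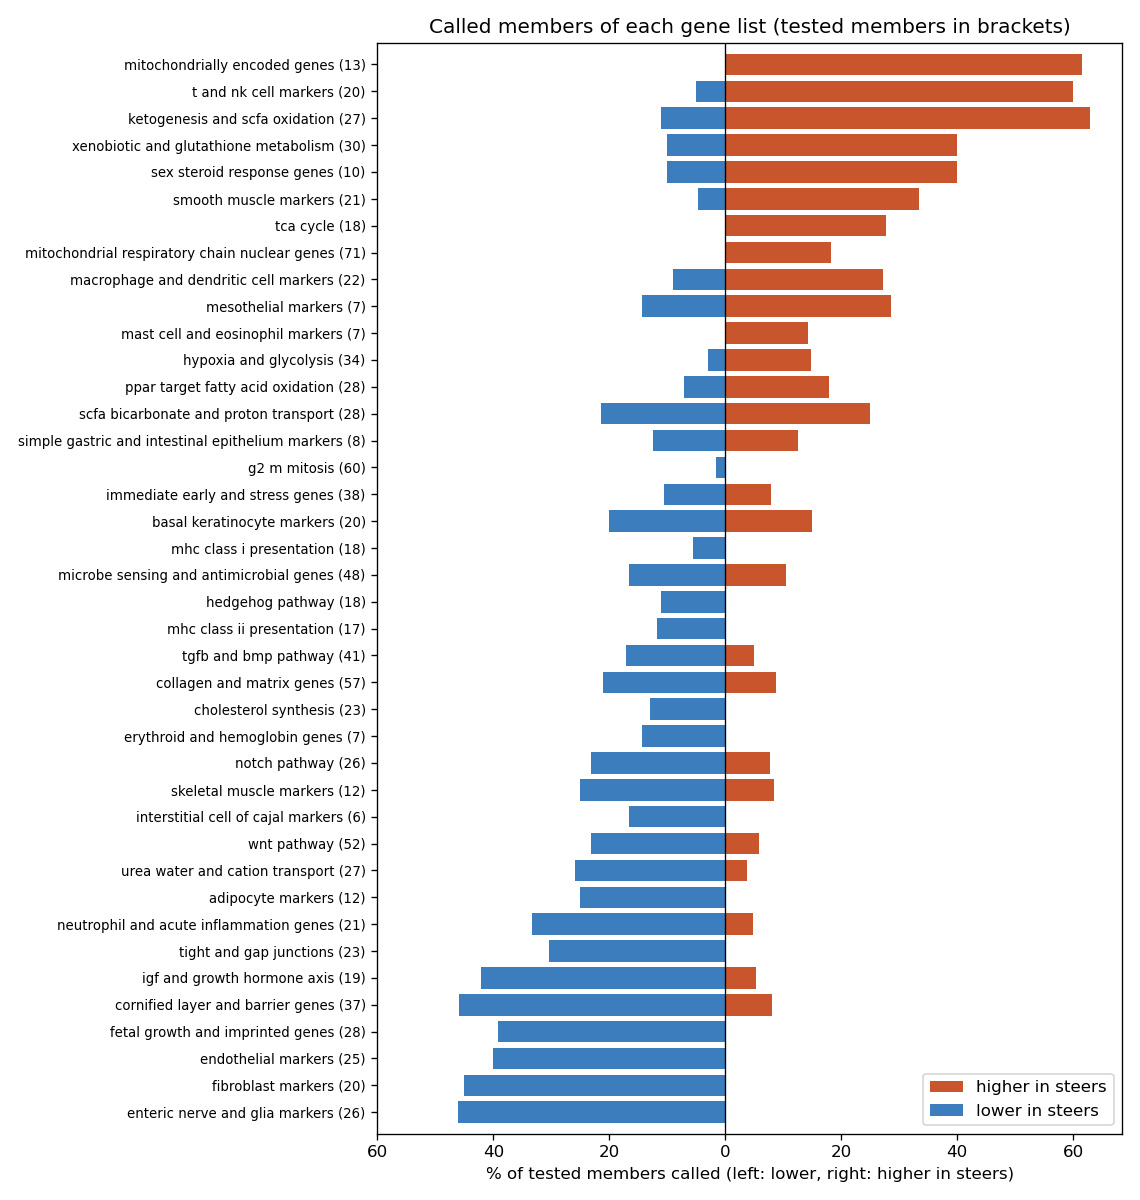
Percentage of tested members called higher (right of 0) or lower (left of 0) in steers for each gene list with at least 1 call, with the tested members in brackets. Mitochondrially encoded genes (8 of 13), T and NK cell markers (12 of 20) and ketogenesis genes (17 of 27) lie at the top, and fibroblast (9 of 20) and enteric nerve and glia markers (12 of 26) at the bottom.

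Of the fetal growth and imprinted list none of 28 rose and 11 fell (0 and 13 adjusted over the list alone; camera adjusted p = 2.62e-11; adjusted p = 0.461 with an estimated correlation). The growth factor IGF2 (chromosome 29, 49395153 to 49422469) fell from 1213 ± 524 to 93.2 ± 16.0 CPM (-3.70 ± 0.37, adjusted p = 0.000325). Its RNA-binding regulator IGF2BP3 fell from 16.0 ± 1.6 to 0.231 ± 0.119, and the imprinted non-coding RNA MEG3 (chromosome 21, 65727804 to 65746033) from 499 ± 273 to 16.3 ± 5.4. In the IGF and growth hormone list 1 of 19 rose and 8 fell (2 and 8 adjusted over the list alone; camera adjusted p = 0.0059; adjusted p = 0.461 with an estimated correlation). Over unshared spans the list did not pass (0.0508). IGFBP2 and IGFBP6 fell by 6.57 ± 0.51 and 2.51 ± 0.37 and IGFBP5 rose by 1.17 ± 0.23. None of 45 S-phase genes was called (camera adjusted p = 0.994, at 0 and 0 adjusted over the list alone), MCM7 being at 132 ± 39 and 125 ± 24 CPM. Of 60 G2/M genes 1, PRC1, fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.344). The PRC1 call, at -1.30 ± 0.37, ended without calf 1, calf 3, steer 1, steer 2 or steer 3 (-1.52 to -0.90 with 1 library left out), with library size only, with limma-voom and with either covariate. The G2/M list passed as higher without calf 3 (adjusted p = 7.6e-05), with limma-voom (0.0362) and with the smooth muscle mean as a covariate (0.00432). The proliferation marker MKI67 was at 68.8 ± 66.4 CPM in calves and 59.4 ± 18.1 in steers (adjusted p = 0.867). Its log2 change was -0.21 and turned to 0.57 without calf 3, which held 155.6 CPM.

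In the Wnt list 3 of 52 members rose and 12 fell (3 and 12 adjusted over the list alone; camera adjusted p = 0.0197; adjusted p = 0.589 with an estimated correlation). The list's call ended without calf 2 (adjusted p = 0.0952) or steer 1 (0.0937) and with the slope on gene span as a covariate (0.2), and without calf 2 and steer 4 (0.102). The ligands WNT3 and WNT4 and the Wnt amplifier RSPO2 had changes of -4.19 ± 0.43, -5.86 ± 0.68 and -3.65 ± 0.41, and the Wnt inhibitor SFRP1 rose by 2.97 ± 0.24. Of 18 hedgehog genes none rose and 2 fell (0 and 2 adjusted over the list alone), among them the target gene GLI1 (-2.54 ± 0.43). The hedgehog list passed camera at adjusted p = 0.0415 (adjusted p = 0.589 with an estimated correlation). It did not pass without calf 2 (0.152), steer 1 (0.12) or steer 4 (0.0577), nor with DESeq2 (0.0757), library size only (0.0628), the stricter filter (0.0664), the gene span slope as a covariate (0.218), unshared spans (0.101) or calf 2 and steer 4 left out (0.162). In the Notch list 2 of 26 rose and 6 fell (2 and 8 adjusted over the list alone; camera adjusted p = 0.0517, and 0.0129 to 0.0226 without calf 1, calf 3 or steer 3). It also passed with DESeq2 size factors (0.0453), no filter (0.0364) and limma-voom (0.0306). HES4 and NOTCH3 had changes of -3.05 ± 0.40 and -1.72 ± 0.32, and HES2 rose by 2.92 ± 0.34. Of 41 TGF-beta and BMP genes 2 rose and 7 fell (2 and 7 adjusted over the list alone; camera adjusted p = 0.771), among them LTBP2 (1.47 ± 0.27), BMP6 (1.89 ± 0.38) and TGFB3 (-1.77 ± 0.26).

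Of 21 smooth muscle markers 7 rose and 1 fell (15 and 1 adjusted over the list alone; camera adjusted p = 0.00179; adjusted p = 0.72 with an estimated correlation and 0.237 with fry). Their mean log2 CPM was 8.64, 8.69, 7.62 and 8.37 in calves 1 to 4 and 9.45, 10.6, 9.9 and 8.05 in steers 1 to 4, so steer 4 lay within the calves. The intermediate filament genes DES and SYNM rose from 3099 ± 1423 to 27910 ± 20580 and from 128 ± 56 to 1425 ± 924 CPM. The contractile regulator CALD1 rose by 2.22 ± 0.50 and the muscle myosin MYH11 by 1.97 ± 0.47, a call lost without calf 1, calf 3, calf 4 or steer 3 (1.68 to 2.31). FLNA, among the 5 most abundant genes called higher, rose by 1.93 ± 0.59 (adjusted p = 0.0495) but passed in only 1 of the 8 fits that left out a library, the one without steer 4. The FLNA call also ended with RLE or upper-quartile factors, the stricter filter, robust dispersion off, limma-voom, either covariate and unshared spans. The smooth muscle covariate is the mean of this list, so a fit with it says nothing on the list or its members. ACTA2, the smooth muscle actin, went the other way, from 1314 ± 392 to 76.9 ± 16.2 CPM (-4.09 ± 0.33, adjusted p = 0.000121), where its close relative ACTG2 shares much sequence.

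Fibroblast markers fell in 9 of 20 cases and none rose (0 and 9 adjusted over the list alone; camera adjusted p = 0.00134; adjusted p = 0.589 with an estimated correlation and 0.062 with fry). COL1A1 fell from 1197 ± 588 to 202 ± 55 CPM, and COL1A2 and VIM changed by -2.02 ± 0.41 and -1.34 ± 0.23. Among 57 collagen and matrix genes 5 rose and 12 fell (5 and 15 adjusted over the list alone; camera adjusted p = 0.0152; adjusted p = 0.93 with an estimated correlation and 0.304 with fry). The microfibril genes FBN2 and MFAP2 fell by 3.83 ± 0.30 and 3.73 ± 0.32, and the matrix glycoproteins TNC and THBS4 rose by 4.25 ± 0.45 and 3.95 ± 0.43. That list no longer passed without calf 2 (adjusted p = 0.22), steer 1 (0.115), steer 4 (0.118) or calf 2 and steer 4 together (0.639). Nor did it pass with the slope on gene span as a covariate (0.236) or over unshared spans (0.245). With the smooth muscle mean as a covariate it passed at 6.29e-06, with 22 of 57 genes lower and 3 higher. The list median was then -0.98, against -0.47 without the covariate. Of 25 endothelial markers none rose and 10 fell (0 and 14 adjusted over the list alone; camera adjusted p = 3.42e-05; adjusted p = 0.461 with an estimated correlation). ECSCR (-2.05 ± 0.28), SOX17 (-1.89 ± 0.33) and TIE1 (-1.70 ± 0.30) were among them. Of 26 enteric nerve and glia markers none rose and 12 fell (0 and 19 adjusted over the list alone; camera adjusted p = 4.15e-10; adjusted p = 0.461 with an estimated correlation). The fall was -4.20 ± 0.50 for PHOX2A, -4.96 ± 0.69 for GAP43 and -2.55 ± 0.35 for SYP.

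Of 12 skeletal muscle markers 1 rose and 3 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.342). The fast troponins TNNI2 and TNNT3 fell from 34.6 ± 22.3 to 0.191 ± 0.180 and from 43.7 ± 14.4 to 6.94 ± 3.30 CPM. The TNNI2 change was -7.51 ± 0.75, and -8.29 without steer 1. Of 12 adipocyte markers none rose and 3 fell (1 and 6 adjusted over the list alone; camera adjusted p = 0.463, and 0.0392 without calf 1). They included THRSP, at -3.16 ± 0.63 and at -2.19 without calf 4, where it was 15.1 CPM against 2.02 to 3.81 in the other calves. Of 7 mesothelial markers 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.813), UPK3B rising by 1.83 ± 0.32 and KRT18 falling by 3.56 ± 0.52. Of 6 interstitial cell of Cajal markers only CD34 changed (-0.92 ± 0.20; 1 and 1 adjusted over the list alone; camera adjusted p = 0.778), a call lost with the smooth muscle mean as a covariate. Of 8 simple gastric and intestinal epithelium markers, LGALS4 rose by 1.36 ± 0.31 and APOA1 fell by 3.84 ± 0.47 (2 and 1 adjusted over the list alone; camera adjusted p = 0.48). In the erythroid list 1 of 7, the transferrin receptor TFRC, fell by 1.55 ± 0.32 (2 and 2 adjusted over the list alone; camera adjusted p = 0.771), a call lost with the smooth muscle mean as a covariate. The globin HBB was at 1.46 ± 1.66 CPM in calves and 0.0974 ± 0.195 in steers (adjusted p = 0.0808), a log2 change of -4.01, or -2.82 without calf 1. It passed without steer 2, with limma-voom and with the smooth muscle covariate. Without steer 2 no steer count was left, so the fitted -9.18 is not a measured size.

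**Figure D3:**
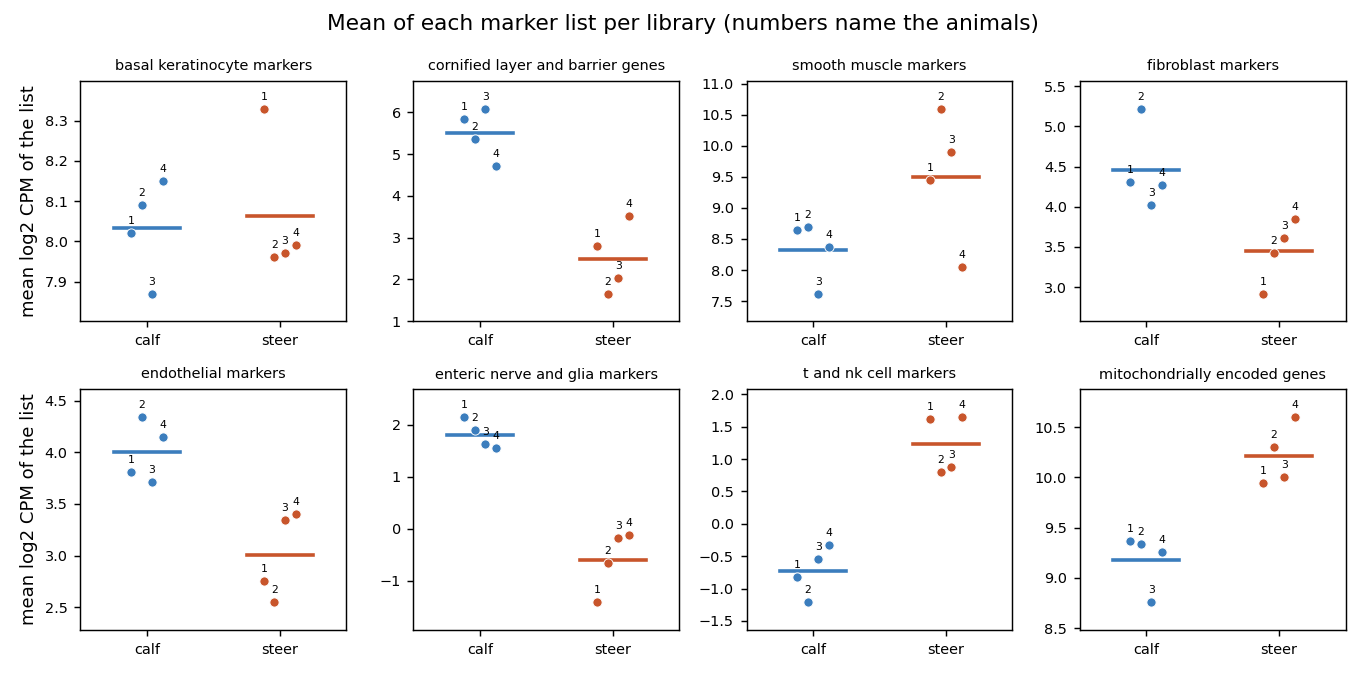
Mean log2 CPM of 8 gene lists in each library (points, numbered by animal), with the group mean as a line and a separate scale in each panel. Smooth muscle means overlap, with steer 4 at 8.05, fibroblast, endothelial and nerve means are lower in all 4 steers, and T and NK cell and mitochondrial means are higher in all 4.

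Of 20 T and NK cell markers 12 rose and 1 fell (13 and 1 adjusted over the list alone; camera adjusted p = 1.2e-06; adjusted p = 0.461 with an estimated correlation). Levels were low: the T cell receptor chain CD3E rose from 0.317 ± 0.220 to 4.57 ± 2.40 CPM (3.84 ± 0.64, adjusted p = 0.00389). CD4 rose from 0.278 ± 0.117 to 2.78 ± 1.27 and CD2 from 0.134 ± 0.066 to 1.77 ± 0.85. The kinase LCK fell from 12.1 ± 3.2 to 4.98 ± 0.38 CPM. CD3D, a T cell receptor chain like CD3E, was not called (log2 change 0.04, adjusted p = 0.982). Of 22 macrophage and dendritic cell markers 6 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.024; adjusted p = 0.639 with an estimated correlation and 0.091 with fry). The list did not pass without steer 4 (adjusted p = 0.226) with the stricter filter (0.144) or with the gene span slope as a covariate (0.0568), or without calf 2 and steer 4 (0.28). CD207, the langerin of Langerhans cells, rose from 0.327 ± 0.215 to 11.3 ± 4.8 CPM, ITGAX by 2.84 ± 0.55 and CSF1R by 1.35 ± 0.29. Of 21 neutrophil and acute inflammation genes 1 rose and 7 fell (2 and 8 adjusted over the list alone; camera adjusted p = 0.0186; adjusted p = 0.589 with an estimated correlation and 0.0531 with fry). That list call ended without calf 1 (0.0682), calf 3 (0.206), calf 4 (0.0611) or steer 2 (0.141), with limma-voom or no filter (0.123 each) or with the smooth muscle mean as a covariate (0.508). CXCR2 fell by 5.27 ± 0.37, and PGLYRP1 changed by -4.78 ± 0.82, or -5.53 without steer 1. S100A9, which keratinocytes also make, fell from 2886 ± 2256 to 66.8 ± 47.6 CPM, a log2 change of -5.43 ± 0.89, and -6.04 without steer 1. Its partner S100A8 fell by 2.65 ± 0.79 (adjusted p = 0.0463), a call that held in only 1 of the 8 fits with a library left out, the one without calf 2, and that ended with limma-voom and with the smooth muscle mean as a covariate.

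None of 10 B and plasma cell markers was called (0 and 0 adjusted over the list alone; camera adjusted p = 0.873), and XBP1 was at 131 ± 36 and 84.5 ± 42.5 CPM (called without steer 4, at -1.02). None of 39 interferon response genes was called (0 and 0 adjusted over the list alone; camera adjusted p = 0.818), and IRF7 was at 72.7 ± 23.6 and 73.4 ± 32.0 CPM. Of the MHC class II list 2 of 17 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.873), IFI30 and CIITA. Of the MHC class I list 1 of 18 fell, CALR (0 and 0 adjusted over the list alone; camera adjusted p = 0.621). All 3 lost their calls without calf 1 (-1.55 for IFI30, -0.87 for CIITA and -1.08 for CALR), calf 3 or steer 3 and with the smooth muscle mean as a covariate. Calls were also lost without calf 4 (IFI30, CALR), steer 1 (CIITA, CALR), steer 2 (IFI30, CALR) or steer 4 (CIITA). That of CIITA also ended without the 50 most abundant genes, without calf 2 and steer 4 together, with limma-voom and with the gene span slope as a covariate. CD74, the class II invariant chain, was at 283 ± 160 and 287 ± 78 CPM. Of 7 mast cell and eosinophil markers FCER1A rose (2.50 ± 0.68; 1 and 0 adjusted over the list alone; camera adjusted p = 0.818), a call lost without calf 1, calf 4, steer 1 or steer 4 (2.14 to 2.96) and without calf 2 and steer 4 together. In the microbe sensing and antimicrobial list 5 of 48 members rose and 8 fell (6 and 8 adjusted over the list alone; camera adjusted p = 0.478, and 0.0261, lower, with the stricter filter). The inflammatory caspase CASP1 (chromosome 15, 3232948 to 3248827) fell from 24.1 ± 1.1 to 0.746 ± 0.108 CPM (-5.01 ± 0.23, adjusted p = 1.54e-05), the smallest adjusted p among the named genes. The protease inhibitor WFDC2 changed by -9.71 ± 1.02, or -10.77 without steer 1. The beta-defensin DEFB1 had no count in calves and 1.24 ± 0.63 CPM in steers, at least 20.2-fold higher at a floor of 3 counts per calf library.

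Of 38 immediate early and stress genes 3 rose and 4 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.907). MT2A rose from 14.9 ± 5.3 to 315 ± 146 CPM and IER3 by 1.65 ± 0.29, and BTG2 fell by 0.95 ± 0.17. Of 34 hypoxia and glycolysis genes 5 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.271), PFKFB4 and ADM rising by 1.97 ± 0.26 and 1.64 ± 0.38, ADM not with library size only. With the smooth muscle mean as a covariate the list passed as higher (0.0363). None of 76 cytosolic ribosomal protein genes changed (0 and 0 adjusted over the list alone; camera adjusted p = 0.618), and RPLP1 was at 8395 ± 3107 and 8292 ± 3562 CPM. Of 10 sex steroid response genes 4 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.0196; adjusted p = 0.461 with an estimated correlation). Without steer 4 (0.0734), without calf 2 and steer 4 (0.0625) or with no filter (0.11) the list did not pass. GREB1, an estrogen target, rose from 0.207 ± 0.146 to 6.49 ± 1.70 CPM, the steroid dehydrogenase HSD17B2 by 2.89 ± 0.39 and PMEPA1 by 1.45 ± 0.23, and the estrogen receptor ESR2 fell by 3.35 ± 0.57.

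Of 342 transcription factors tested, 69 changed, 27 higher and 42 lower (28 and 42 adjusted over the list alone). That is 20.2% of the factors against 16.8% of the other genes (two-sided Fisher's exact p = 0.108), and 45 changed without calf 1. HAND1 rose from 0.0651 ± 0.0810 to 11.7 ± 10.4 CPM (7.37 ± 1.15, and 6.75 to 8.51 with 1 library left out). BHLHE41 rose by 3.96 ± 0.37, HES2 by 2.92 ± 0.34 and RUNX3 by 2.75 ± 0.64. Of the counted span of BHLHE41, 67.2% lies in another gene, SSPN. The call of RUNX3 ended without calf 1 (2.65, and 3.35 without calf 3). EYA2 fell by 5.53 ± 0.79, the squamous and foregut factor BARX2 by 4.29 ± 0.58 (211 ± 68 to 10.8 ± 9.1 CPM). IKZF2 fell by 4.26 ± 0.38, TWIST2 by 3.37 ± 0.76, ESR2 by 3.35 ± 0.57 and TFAP2C by 3.30 ± 0.31. Without steer 4 the changes were -5.05 for BARX2 and -4.65 for TWIST2.

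Over the 44 lists, 21 passed camera at its preset correlation of 0.01, 9 higher and 12 lower, and none passed with an estimated correlation (smallest adjusted p 0.461). Of the 35 ways to split the 8 libraries 4 against 4, 8 gave at least as many lists, the real one included. Fry, which asks whether a list moves on balance in 1 direction, passed 14 lists, 13 of them past camera, and 8 lists past camera did not pass it. The mean log2 CPM of 19 lists did not overlap between the groups, 18 of them past camera, which gives the smallest two-sided exact permutation p that 4 against 4 allows, 0.0286 (0.0662 adjusted over the 44 lists). The collagen, smooth muscle and tight junction lists passed camera although their means overlapped. Median, mean and tested direction differed in sign for the immediate early, basal keratinocyte, G2/M, TGF-beta, skeletal muscle and interferon lists, none of which passed camera.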

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

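The counts over other splits of the animals were planned; the tests on smooth muscle, squamous and mitochondrial genes were chosen after those results were seen. In 492 groups of 4 libraries (2 groups for each measure), 41 had a highest or lowest library whose gap to the next, divided by the group's range, passed Dixon's 95% critical value. For normally distributed values chance gives about 24.6, 1 in 20 groups. Genes were tested as CPM and not as logs, so that rate is uncertain for them. The flagged groups comprised 36 of 386 for genes and 5 of 106 for other measures. Calf 2 stood apart in 9, calf 3 in 8, steer 2 in 7, steer 4 in 6, calf 4 in 5, steer 3 in 3, steer 1 in 2 and calf 1 in 1.

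Calf 2 was highest for LOR (160 CPM), ASPRV1 (34.5), IGFBP2 (586), TWIST2 (27.1), TNC (9) and TSLP (1.76), lowest for CDHR4 (0.502) and IFI30 (19.1), and highest for the hedgehog list mean (3.37 log2 CPM, the other calves 2.9 to 2.97). Calf 3 was highest for SLC16A1 (103 CPM, the others 53 to 54.7), SLC9A3 (361), CA1 (9.13), CERS3 (11.5), SDHD (68.8) and KRT36 (0.968), and lowest for FLNA (1418) and VIM (195). Calf 4 was highest for ACSM1 (14.3 CPM), THRSP (15.1), ALDH3A1 (7.2) and DEFB10 (0.0837, the others at 0), and lowest for CYP2C87 (39.3). CASP1 was lowest in calf 1, at 22.5 CPM against 24.5 to 24.9.

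Among steers, steer 4 was highest for SLC9A3 (103 CPM, the others 6.46 to 11.6), CYP51A1 (48.3), GJB6 (3.16), IL1A (4.89), KRT36 (6.7) and CRNN (0.0351, the others at 0). Steer 3 was highest for URAD (37.8 CPM), IKZF2 (1.34) and FMO2 (0.0559, the others at 0). Steer 2 was highest for TNNT3 (11.9 CPM), HBB (0.39, the others at 0), SLC9A4 (0.0557, the others at 0) and the share of counts in the 10 most abundant genes (17.6%, the others 11.4% to 12%). It was lowest for IGF2BP3 (0.0557 CPM), the G2/M list mean (2.41 log2 CPM) and the neutrophil list mean (-0.0542 log2 CPM, the others 1.1 to 1.21). Steer 1 was highest for IFI30 (26.7 CPM) and the basal keratinocyte mean (8.33 log2 CPM, the others 7.96 to 7.99).

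Of the 35 splits of the 8 animals 4 against 4, 1, the real one, gave as many changed genes (2752, highest other 0). The same held for higher genes (1257, highest other 0), lower genes (1495, highest other 0), genes changed at least 2-fold (2292, highest other 0) and changed transcription factors (69, highest other 0). Every other split mixed calves with steers, which puts the difference between them into the spread within groups. Such splits can hardly call genes, so they cannot exclude chance for these counts. For gene lists past camera, 8 of the 35 splits gave at least the real 21, with 23 the highest of the other splits, so chance cannot be excluded for that count.

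The mean of the smooth muscle markers was higher in steers 1 to 3 than in any calf, and not in steer 4. The markers' changes within groups correlated at 0.7, which goes with a varying amount of muscle layer in the tissue pieces. A lower share of epithelium in the steer pieces would raise the endothelial, fibroblast and nerve lists. Their mean shifted by -1.46 on the log2 scale (two-sided exact permutation p = 0.0286). CPM are shares of all counts, so more smooth muscle would also lower these lists. With the smooth muscle mean as a covariate, 7 of 25 endothelial, 6 of 20 fibroblast and 12 of 26 nerve markers were lower. None was higher, and the list medians were -0.75, -1.07 and -2.57. Steer 4, with its smooth muscle mean within the calves, also lay below every calf for these lists. This argues against more smooth muscle as the whole cause of their fall. Age differs between the groups, so the shift cannot decide on the share of epithelium, which stays open. The smooth muscle shift exceeded the mean shift of these lists by 2.63 (exact permutation p = 0.0286). It exceeded the endothelial shift alone by 2.16 (exact permutation p = 0.0571). Age, castration and diet were not tested and stay open, as does the fall of ACTA2 against the other markers.

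KRT4, KRT13 and others of the cornified list, 17 of 37 members, fell in steers, and 3 rose (adjusted p = 0.461 with an estimated correlation). A lower share of epithelium as the whole cause is argued against by the basal keratinocyte list. Its median log2 change was 0.06 (95% bootstrap interval over genes, not animals, -0.55 to 0.53). Its library means were 7.87 to 8.15 log2 CPM in calves and 7.96 to 8.33 in steers (exact permutation p = 0.8). Members moved both ways, 3 rising and 4 falling, so the list does not show an unchanged basal layer. With the smooth muscle mean as a covariate, 14 of 37 cornified genes fell and 5 rose. The median of the cornified list was then -0.87, against -1.49 without the covariate. Its camera adjusted p was 0.00611, but 0.693 with an estimated correlation. A part of the fall that goes with the smooth muscle mean therefore stays open. A few abundant genes taking the counts, as the whole cause, are argued against by single genes of the cornified list, of which 15 of 35 fell with the 50 most abundant genes left out. The list then had a camera adjusted p of 3.53e-08, but adjusted p = 0.496 with an estimated correlation. Age, castration, diet and the site sampled within the rumen were not tested and stay open.

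Of the mitochondrially encoded genes 8 of 13 rose in steers, and of nuclear respiratory chain genes 13 of 71, with none lower (adjusted p = 0.461 and 0.693 with an estimated correlation). More muscle layer as the whole cause is argued against by the mitochondrially encoded genes, of which 6 of 13 rose with the smooth muscle mean as a covariate (median log2 change 1.09, and 1.05 without it; list camera adjusted p = 0.000536, but adjusted p = 0.693 with an estimated correlation). A length trend as the whole cause is argued against by the nuclear genes, of which 17 of 71 rose with the gene span slope as a covariate (median 0.37; list camera adjusted p = 0.000126, but adjusted p = 0.631 with an estimated correlation), and a part stays open. Loss of cytoplasmic RNA in the steer samples, as the whole cause, is argued against only weakly by the nuclear list. Its median log2 change was 0.57 (95% bootstrap interval over genes, not animals, 0.5 to 0.69), where all genes had 0.037. Its members correlated at 0.69 within groups, and fry gave an adjusted p of 0.091. Its library means did not overlap (exact permutation p = 0.0286), but calf 4 at 7.04 and steer 3 at 7.09 log2 CPM were close. A part therefore stays open. Age, castration and diet were not tested and stay open.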

How the results depend on the processing

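Halved counts, the smooth muscle mean and gene span slope as covariates, calf 2 and steer 4 left out together, and unshared spans were chosen after the data were seen. No gene called changed sign under any setting. The groups did not overlap for 92.6% of called genes, so leaving out 1 library could hardly turn a sign. Of 180 called named genes, 143 kept their call in each of the 8 fits without 1 library. Many of these were chosen for large changes or small p. Of all 2752 calls, 60.8% (without calf 1) to 88.3% (without steer 4) were kept. Library size only gave 835 higher genes. An adjusted p under 0.01 gave 1111 changed genes (406 higher, 705 lower, 1085 at least 2-fold) and 30 transcription factors, and glmTreat against a 2-fold change gave 893 (298 higher, 595 lower, all 893 at least 2-fold) and 22 factors; both are stricter by construction. DESeq2 gave 4210 changed genes (1956 higher, 2254 lower), and the cause was not tested. Unshared spans gave 45 factors, with fewer genes tested. Leaving out 1 library gave 1734 (calf 1) to 3257 (steer 4) changed genes, 705 to 1473 higher genes and 45 to 82 factors, and 17 to 22 lists. The smooth muscle covariate gave 2702 changed genes but kept 66.5% of the calls. An estimated correlation left 0 lists past camera (44 tested, smallest adjusted p 0.461), and fry passed 14. The replicate numbers name different animals, and same-number deviations correlated at 0.2, 0.083, -0.095 and -0.27, so the numbers do not pair the samples. Calves 1 to 4 correlated best with steers 1, 3, 4 and 1, not each with its own number. A replicate block gave 1831 changed genes (785 higher) and left 21 lists. The promoter motif tests and their alternatives of window, calls and covariates were not run. With 4 animals per group, 2-fold changes were mostly missed in simulated counts (10% recovered). Far fewer genes changed in that simulation than were called here, so recovery in these data can differ.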

Other observations

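The families and genes below, and their tests, were chosen after their values were seen, and adjusted p is over 11 families. Several family members also belong to the fixed lists above, such as KLK10 and KLK12 in the cornified list. Connexins of the junction list are a further case. The family tests are therefore not separate support for those lists. Kallikreins, proteases that help shed surface cells of squamous epithelia, fell in all 7 tested members (camera adjusted p = 8.59e-08; adjusted p = 0.0979 with an estimated correlation). KLK10 fell from 322.9 ± 243.1 to 1.455 ± 0.447 CPM and KLK12 from 125.9 ± 113.9 to 0.628 ± 0.199 (log2 change -7.65, and -7.05 without calf 3). KLK11, at -3.92, lost its call without calf 1 (-3.36) and was at -4.94 without steer 3. With 3 other scalings 7 kallikreins stayed lower. Of 12 connexins 6 fell and none rose (camera adjusted p = 0.000207; adjusted p = 0.0979 with an estimated correlation), among them the vessel connexins GJA4 (-1.70 ± 0.29) and GJA5 (-1.73 ± 0.33), and with 1 library left out 5 or 6 fell and none rose, except 1 without steer 2. Keratins went both ways, with 9 of 25 higher and 6 lower (camera adjusted p = 0.861; 8 and 7 with library size only, 6 and 4 without calf 1). KRT7, a keratin of simple epithelia, fell from 52.1 ± 18.1 to 0.742 ± 0.249 CPM, and the hair keratin KRT35 rose from 1.13 ± 0.63 to 14.3 ± 6.0. KRT14, the basal partner of KRT5, rose by 1.69 ± 0.41, a call lost without calf 1, calf 2 or calf 3 (1.49 to 1.61) and with the smooth muscle mean as a covariate. Of 6 beta-defensins 4 rose (camera adjusted p = 4.34e-06, and 0.0979 with an estimated correlation), and 3 to 5 rose without 1 library. Among them DEFB7 rose from 0.0273 ± 0.0322 to 6.89 ± 4.36 CPM (log2 change 7.92, and 8.74 without calf 4). The calf mean of DEFB7 lay below the floor of 3 counts per library (0.0615 CPM), so the size is uncertain.

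Other single genes moved far. TERT, the telomerase catalytic subunit, fell from 65.3 ± 16.8 to 7.42 ± 4.16 CPM (adjusted p = 0.000809), and HOXD9 by 3.47 ± 0.51 (-4.15 without steer 3). The epidermal S100A7 changed by -6.81 ± 1.11 (-7.94 without steer 1, -6.20 without calf 3), while S100A4 rose from 283 ± 122 to 1328 ± 656 CPM. Of T cell genes, IL7R, which is outside the T and NK cell list, rose by 4.82 ± 0.61 (5.44 without calf 2). ICOS, a member of that list, rose by 4.15 ± 1.02, a call lost without calf 4 (4.16), with 5.67 without calf 3. CD3D, also a member of that list, was at 5.57 ± 4.54 CPM in calves and 5.71 ± 6.82 in steers (adjusted p = 0.982). Its log2 change was 0.04, but -1.18 without steer 4 and 0.64 without calf 3, neither called.

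The 34 listed genes whose span lies wholly inside other spans had no count in any library, so these data give no level for them. They include the cornified envelope gene IVL, the desmogleins DSG1 and DSG3, the regulators PPARG, ZNF750 and SOX2, the oxidation enzyme ECHS1, the muscle gene PLN and the immune genes AIF1, CD86, CXCL10 and NFKBIA. In all, 470 wholly shared genes carry names other than those of uncharacterised loci, microRNAs, tRNAs and small nucleolar RNAs.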
